A study of Homo sapiens with 6 samples.

How the data were processed

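In DU145 cells, 6 libraries were analysed, 3 transfected with a control siRNA and 3 with an siRNA against RCC2. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with a micro-scale column kit and libraries were made from total RNA with an MGI kit; how ribosomal RNA was removed, whether strand was kept, the read length and the siRNA sequences are not given in the sources used here. Per the submitters' processing notes, the tools were Bowtie2, RSEM and DESeq2 and the genome build was GRCh38, with no versions. The authors deposited 1 count table per library, with whole-number counts for 50868 genes, each with a gene name and a locus. The RSEM estimates may therefore have been rounded before deposit. RSEM shares reads among genes with like sequence, so values of paralogs, pseudogenes and overlapping genes depend on that sharing. The pseudogene EEF1A1P5, for example, had 3.79 times the counts of EEF1A1.

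Gene types, lengths, strands and sequences came from GENCODE release 29 on GRCh38, which holds 50111 of the gene identifiers, 94.8% of them at identical coordinates. Coordinates in the text are those of the deposited files. Shared sequence was measured as the percent of all 50-base stretches of a gene's longest transcript that occur in transcripts of other genes. Of 718 genes in the fixed lists, 1 has no row in the files used.

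Total counts were 19808215, 18206357 and 18791049 in siCtrl replicates 1 to 3 and 17377191, 19895431 and 19111049 in siRCC2 replicates 1 to 3. At this depth 1 CPM is about 17 to 20 reads, so genes below 1 CPM rest on few reads. Pairs of libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom from 8.79 to 52.5), so each library was counted once. The biological coefficient of variation was 16.6%.

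Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the group design, libraries scaled by TMM, and the groups compared with the quasi-likelihood F-test (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are siRCC2 over siCtrl. The standard error is the log2 fold change divided by the square root of F. CPM values are TMM-scaled, with SD over 3 libraries. The design, the alternatives, the rule for naming genes and 36 gene lists were fixed before the data were examined. Lists with at least 5 tested members (32) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. The text names RCC2, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 1 CPM, a symbol that is neither a clone name nor a pseudogene and no overlap of the groups, 7 Hedgehog genes, the 5 most abundant genes (MT-CO1, MT-RNR2, MT-ND4, MT-CO2 and GAPDH), and up to 4 members of each list with the smallest p. Some of these genes and 1 list are not reported here.

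The alternatives were other scalings (DESeq2 size factors, upper quartile, total count), DESeq2 1.42.0 and limma-voom in place of edgeR, 3 other filters, protein-coding genes only, the replicate number as a block, leaving out each library, and a stricter threshold. Offsets for gene length and for GC content, a restriction to genes without the 6-mer, and 8 further lists were added after the data were seen. For the motif search, the longest coding transcript of each gene with a 3′ UTR of at least 100 bases was used, and 7-mers present in at least 50 genes were scored by regression of the log2 fold change on their presence.

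The test was checked on simulated counts for the 16536 genes, of which 200 were changed by known folds. It recovered 8% of the genes changed 1.5-fold, 44% of those changed 2-fold, 82% at 3-fold and 88% at 4-fold, and 11 of its 122 calls (9.02%) were unchanged genes. The list test called a planted list of rising genes (adjusted p = 4.48e-20) and 0 of 100 random lists. Only 200 genes were changed there, against 41.8% of tested genes called in the data, so these rates do not carry over to the data. The simulated genes were drawn independently of each other, so the random lists do not check the preset correlation. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.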

Results

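Gene expression was measured by RNA sequencing in DU145 cells, an androgen-independent human prostate cancer line, after transfection with a control siRNA or with an siRNA against RCC2. RCC2 is a member of the RCC1 repeat family that binds centromeres and acts on small GTPases. The series asks, per its title, what RCC2 does for the growth and movement of prostate cancer cells and whether the Hedgehog pathway with its transcription factor GLI1, and stem-like cells, take part. Each group had 3 libraries, called siCtrl and siRCC2 replicates 1 to 3, with total counts from 17377191 to 19895431. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

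RCC2 (ENSG00000179051, GRCh38 chromosome 1, 17406760 to 17439724, minus strand) was lower in each siRCC2 library than in each siCtrl library. Its counts were 3998, 3598 and 3702 in siCtrl replicates 1 to 3 and 980, 1117 and 1045 in siRCC2 replicates 1 to 3. The level fell from 194 ± 3.84 to 57.2 ± 2.25 CPM (SD, n = 3 libraries each), a log2 fold change of -1.76 ± 0.07 (SE; edgeR adjusted p = 2.00e-05). Of the 8 RCC2 pseudogenes with a row, RCC2P6 had the most counts, between 1 and 8 per library, and 2.5% of the 50-base stretches of the longest RCC2 transcript occur in transcripts of other genes.

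RCC2 siRNA moved a large part of the transcriptome. Of 16536 genes tested, 6911 (41.8%) changed at an adjusted p under 0.05, with 3423 higher and 3488 lower in siRCC2. Changes of at least 2-fold were found in 1993 genes, of which 804 were higher and 1189 lower. The values of the 2 groups did not overlap in 9155 genes (55.4%), against the 10% that chance gives for 3 libraries against 3. The first principal component of log CPM held 62.3% of the variance and separated the groups. The second held 16.4% and set siRCC2 replicate 1 (41.5) apart from siRCC2 replicate 2 (-13.3) and replicate 3 (-35.2). Without siRCC2 replicate 1, 7565 genes changed, and 6410 of them were among the 6911 with the same direction.

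The largest rises included TXNIP, an inhibitor of thioredoxin and of glucose uptake (chromosome 1, 145992435 to 145996600), which rose from 1.86 ± 0.182 to 31.6 ± 3.32 CPM, a log2 fold change of 4.08 ± 0.14 (SE; adjusted p = 2.00e-05). EOMES, a T-box transcription factor, rose from 0.913 ± 0.0678 to 8.98 ± 0.581 CPM (3.29 ± 0.16 on the log2 scale). PYGM, the muscle glycogen phosphorylase, rose by 2.92 ± 0.30, and the retinol carrier RBP4 by 3.19 ± 0.40. ABCC9, GSDMC, APBB1IP and PRRG2 rose by 3.04, 2.89, 2.88 and 2.81 from levels below 0.3 CPM. The highest fold change, 4.47 ± 0.42, was that of FBXW10, and CDRT1 rose by 3.13 ± 0.19, but 56.9% of the 50-base stretches of FBXW10 also occur in CDRT1. Together with AC005324.3, which overlaps CDRT1, they rose from 3.11 ± 0.608 to 59.7 ± 26.1 CPM. The values of H3C12 (3.76) and RPPH1 (2.96), the RNA of ribonuclease P, are uncertain for the same reason. H3C12 shares 62.8% of its 50-base stretches with the overlapping H2AC17, and the pair summed changed by only 0.61. RPPH1 lies entirely within another annotated transcript.

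The largest falls included hair-type keratins. KRT81 (chromosome 12, 52285913 to 52291534) fell from 164 ± 7.18 to 7.58 ± 1.31 CPM, a log2 fold change of -4.43 ± 0.14 (adjusted p = 1.68e-05), and KRT83 had a log2 fold change of -5.09 ± 0.46. KRT81 shares 38.4% of its 50-base stretches with KRT86, and the sum of KRT81, KRT83 and KRT86 fell from 188 ± 7.34 to 10.8 ± 1.68 CPM. FUT1, the fucosyltransferase of the H antigen, fell from 12.4 ± 0.614 to 0.742 ± 0.262 CPM (-4.07 ± 0.23). CYFIP2, a subunit of the actin-regulating WAVE complex, fell from 26.6 ± 2.17 to 2.23 ± 0.486 CPM (-3.57 ± 0.18). HES7 (-3.78), the hormone gene SPX (-3.24), TM6SF1 (-3.21), the receptor gene TNFRSF9 (-3.18) and KLHDC7B (-3.11) fell too. VWA5B2 (-3.22) overlaps EIF2B5 (-1.11) and ALG3, and MYZAP (-3.28) shares 70.3% of its stretches with GCOM1, with which its sum changed by -1.36. A short gene model named C11orf71 had a log2 fold change of -4.96, but the sum of the 2 gene models of that name was 0.81 higher, so the direction for C11orf71 is uncertain.

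Hedgehog genes moved in both directions. SUFU, which holds GLI proteins back (chromosome 10, 102503987 to 102633535), fell from 33.1 ± 2.61 to 11 ± 0.319 CPM (log2 fold change -1.59 ± 0.10, adjusted p = 8.75e-05). GLI1, a transcription factor of the pathway and one of its targets (chromosome 12, 57460135 to 57472262), fell from 6.47 ± 0.202 to 3.04 ± 0.313 CPM (-1.09 ± 0.14, adjusted p = 0.00115), lower in 3 of 3 siRCC2 libraries. GLI3 fell by 1.04 on the log2 scale, with a standard error of 0.21 (adjusted p = 0.00703). Its call was lost by DESeq2 with the replicate number as a block (adjusted p = 0.0650). The receptor PTCH1 (-0.22 ± 0.10, adjusted p = 0.128) and GLI2 (-0.10 ± 0.08, adjusted p = 0.348), the most abundant GLI gene, did not pass the threshold. SMO rose by 0.31 ± 0.09 (adjusted p = 0.0322), a call lost without each of 5 of the 6 libraries in turn (adjusted p from 0.0561 to 0.127) and kept without siRCC2 replicate 3 (0.0213). HHIP had 2, 2 and 3 counts in siCtrl and 0 in each siRCC2 library and was not tested. Of 24 tested pathway components, 3 rose, 8 fell and 13 did not pass, with the same counts when adjusted over the list alone. The cilium-associated genes EVC2 (-1.11) and GPR161 (-1.32) and the ligand release factor DISP1 (-1.25) were among those that fell. Compared with other genes, the list did not stand apart (camera adjusted p = 0.112, and 0.0256 with genes of at least 1 read kept). Of the 7 that fell and whose 3′ UTR could be searched, 3 hold there a 7-base match to the sequence motif described below. SUFU and GPR161 are among them, and GLI1 and GLI3 hold none. GLI1 does hold the motif's shared 6-mer, TCTGGA, elsewhere in its transcript, but 9153 of the 12304 genes searched hold it somewhere in theirs.

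**Figure D1:**
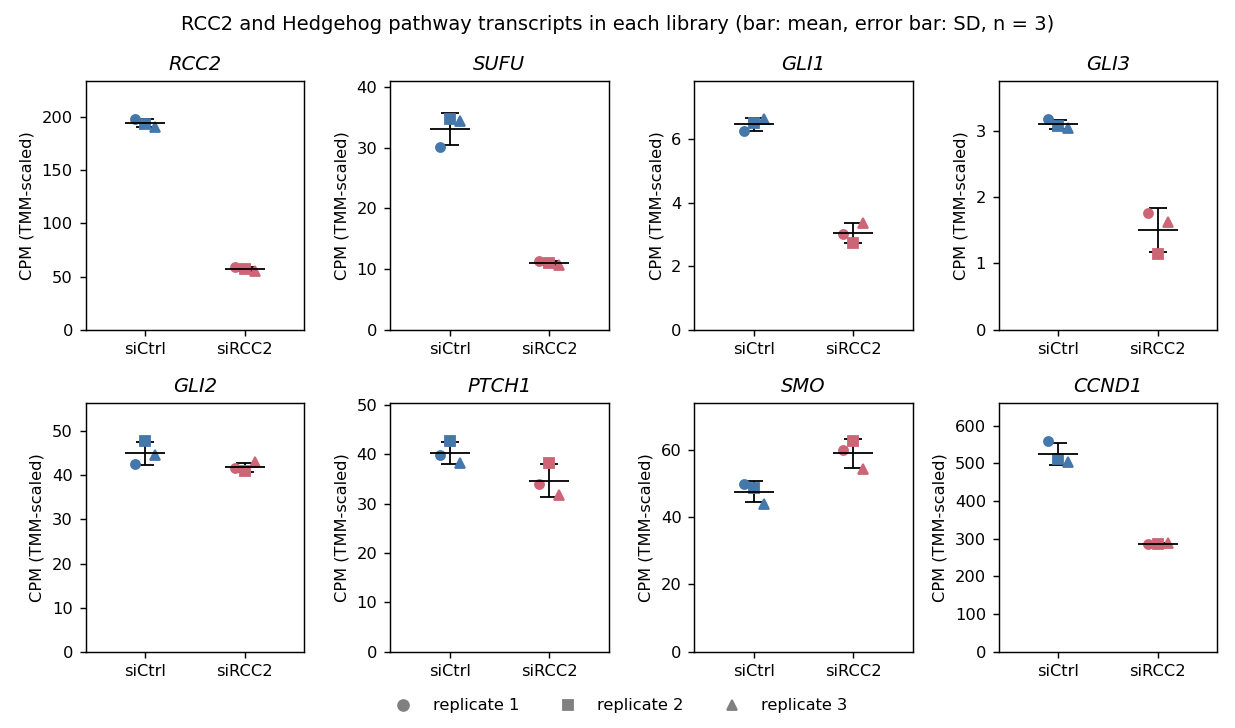
TMM-scaled CPM (vertical axes, each from 0) of RCC2, 6 Hedgehog pathway genes and CCND1 in each library; points are libraries, horizontal bars the group means and error bars the SD (n = 3 per group). RCC2 lies at 194 CPM in siCtrl and 57.2 in siRCC2, GLI1 at 6.47 and 3.04, and GLI2 at 44.9 and 41.8.

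Genes described as GLI targets also split. Of 20 tested, 8 rose, 4 fell and 8 did not pass, and 9 rose and 4 fell when adjusted over the list alone. The list leaned up, with a median of 0.41. It did not stand apart from other genes (camera adjusted p = 0.486) but passed by fry, upward (adjusted p = 0.00263). CCND1, which encodes cyclin D1, fell from 525 ± 30.1 to 286 ± 1.68 CPM (-0.88 ± 0.06), and the phosphatase gene CDC25B fell (-1.04 ± 0.10). The transcription factor genes SOX9 (1.51 ± 0.15) and SNAI1 (0.92 ± 0.10) rose. Among 17 stem-like cell markers, 4 rose, 5 fell and 8 did not pass (5 rose and 6 fell when adjusted over the list alone). The chemokine receptor gene CXCR4 rose by 1.26 ± 0.11, while ALDH1A3 (-0.68 ± 0.08) and NES (-1.07 ± 0.19) fell. The median of this list was -0.24, its mean 0.09 and the direction of its test up (camera adjusted p = 0.948). The list and that of GLI targets hold MYC, which had 133, 59 and 1288 counts in siRCC2 replicates 1 to 3. The mean and direction therefore lean in part on 1 library. SOX2, NANOG, POU5F1, PROM1 and ALDH1A1 had at most 4 counts in any library and were not tested.

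The cell cycle lists did not stand apart from other genes by camera. Of all 16536 genes tested 41.8% changed, the share to set beside the counts that follow. Of 29 DNA replication genes, 6 rose, 7 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.987). The flap endonuclease gene FEN1 rose (0.98 ± 0.07), and E2F2 (-1.27 ± 0.09), MCM10 (-1.04 ± 0.15) and CDC45 (-0.65 ± 0.09) fell. Of 27 mitosis genes, 4 rose, 2 fell and 21 did not pass, likewise the same over the list alone (camera adjusted p = 0.948). KIF20A (0.60 ± 0.07), CCNB2 (0.52 ± 0.07) and TPX2 (0.32 ± 0.06) rose and UBE2C (-0.82 ± 0.07) fell. The medians of both lists changed sign between scalings, from -0.07 to 0.01 for replication and from -0.08 to 0.01 for mitosis. The chromosomal passenger complex and its centromere partners, with which RCC2 works, had 3 of 14 genes up and 0 down (camera adjusted p = 0.567), among them CDCA8 (0.37 ± 0.08). In the RCC1 repeat family, 2 rose and 5 fell of 14 (camera adjusted p = 0.902). RCC1L rose (1.25 ± 0.11), and HERC5 (-1.23 ± 0.14) and RCCD1 (-0.67 ± 0.12) fell. Of 15 cell cycle inhibitors and senescence genes, 4 rose and 5 fell (camera adjusted p = 0.984). CDKN2C, which encodes an inhibitor of CDK4 and CDK6, rose (1.37 ± 0.08), as did IGFBP3 (2.65 ± 0.23), while GDF15 (-2.32 ± 0.15) and the lamin gene LMNB1 (-0.80 ± 0.08) fell. In these 3 lists the counts were the same when adjusted over the list alone.

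Genes of cell shape and movement changed in both directions, and their lists did not pass camera in the main test. By fry, which asks whether a list moves on balance one way, 3 of these lists passed, each downward. They were the mesenchymal (adjusted p = 0.00225), epithelial (adjusted p = 0.00412) and YAP and TEAD lists (adjusted p = 0.000140). The integrin and focal adhesion list did not pass by fry (adjusted p = 0.113). Of 19 mesenchymal genes 4 rose and 6 fell (the same over the list alone; camera adjusted p = 0.631). SNAI1 and SNAI2 (1.01 ± 0.14) rose, and the matricellular genes CCN1 (-0.75 ± 0.07) and CCN2 (-1.14 ± 0.06) fell. Of 21 epithelial genes 4 rose and 9 fell (4 and 10 over the list alone; camera adjusted p = 0.160). KRT7 fell from 3588 ± 116 to 1636 ± 203 CPM (-1.13 ± 0.10), CDH3 (-0.73 ± 0.09) and CLDN7 (-1.36 ± 0.19) fell, and KRT8 rose (0.66 ± 0.06). Of 25 integrin and focal adhesion genes 6 rose and 3 fell (5 and 3 over the list alone; camera adjusted p = 0.624). The caveolin gene CAV1 (0.69 ± 0.06) rose. The median of this list was 0.05 and became -0.02 with total counts alone as the scaling. Of 18 YAP and TEAD targets 4 rose and 8 fell (5 and 9 over the list alone; camera adjusted p = 0.0541), with CRIM1 (-1.23 ± 0.07), FJX1 (-1.15 ± 0.06) and AJUBA (-1.05 ± 0.06) lower. That list passed without siRCC2 replicate 1 (0.0216), siRCC2 replicate 3 (0.0495) or siCtrl replicate 3 (0.0498), and with total counts alone (0.0370), GC offsets (0.0293) or genes of at least 1 read kept (0.00364).

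Genes of cholesterol and fatty acid synthesis rose together. Of 26 tested, 21 rose and 2 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 1.00. The sterol synthesis genes MSMO1 (1.58 ± 0.08) and LSS (1.17 ± 0.06) and FASN, the fatty acid synthase (1.30 ± 0.07), rose. The list stood above other genes (camera adjusted p = 6.14e-15, and adjusted p = 0.0532 with an estimated correlation). Of its 24 members whose 3′ UTR could be searched, 8 hold a match to the motif.

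NF-kB and inflammatory genes fell. Of 19 tested, 14 fell and 2 rose, the same over the list alone, with a median of -1.05. NFKB2, a subunit of NF-kB, fell from 166 ± 1.41 to 80.3 ± 5.77 CPM (-1.05 ± 0.07), the cytokine LIF from 243 ± 6.36 to 110 ± 10.4 CPM (-1.14 ± 0.08), and CXCL2 (-1.35 ± 0.10) and TNFAIP2 (-1.19 ± 0.12) fell as well. The list stood below other genes (camera adjusted p = 3.02e-05, and adjusted p = 0.106 with an estimated correlation), and 3 of its 14 fallen genes hold the motif. Of 27 interferon-stimulated genes 14 fell and 1 rose, the same over the list alone, with a median of -0.70. The transcription factor gene STAT2 (-1.36 ± 0.10) and the antiviral genes OASL (-1.74 ± 0.16), OAS3 (-0.96 ± 0.09) and HERC5 fell (camera adjusted p = 0.00201, and adjusted p = 0.157 with an estimated correlation). Of the 12 fallen genes that could be searched, 2 hold the motif.

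Of 24 unfolded protein response genes 12 fell and 3 rose (13 and 5 over the list alone), with a median of -0.34. Of the members with the smallest p, ASNS, asparagine synthetase, fell from 448 ± 17.6 to 64.6 ± 3.98 CPM (-2.80 ± 0.07, adjusted p = 1.68e-05). DDIT4, an inhibitor of mTORC1, fell from 767 ± 30.7 to 169 ± 13.7 CPM (-2.18 ± 0.08). CHAC1, which breaks down glutathione, had a log2 fold change of -2.21 ± 0.09, and the phosphatase subunit gene PPP1R15A one of -1.04 ± 0.07. The 3 that rose, named after their values were seen, were DNAJB9 (1.15 ± 0.10), CALR (0.72 ± 0.10) and CRELD2 (0.64 ± 0.10), which act in protein folding in the endoplasmic reticulum. The list stood below other genes (camera adjusted p = 5.98e-05, and adjusted p = 0.30 with an estimated correlation), and 1 of the 9 fallen genes that could be searched holds the motif. Of 20 p53 targets 11 fell and 1 rose (13 and 3 over the list alone), with a median of -0.44 (camera adjusted p = 0.00385, and adjusted p = 0.30 with an estimated correlation). DU145 is known to carry mutant p53. TNFRSF10B, a death receptor gene, fell from 273 ± 9.94 to 74.9 ± 1.35 CPM (-1.86 ± 0.06), and GADD45A (-1.36 ± 0.10), DDB2 (-1.27 ± 0.11) and TP53INP1 (-0.76 ± 0.13) fell. Of the 11, 5 hold the motif.

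**Figure D2:**
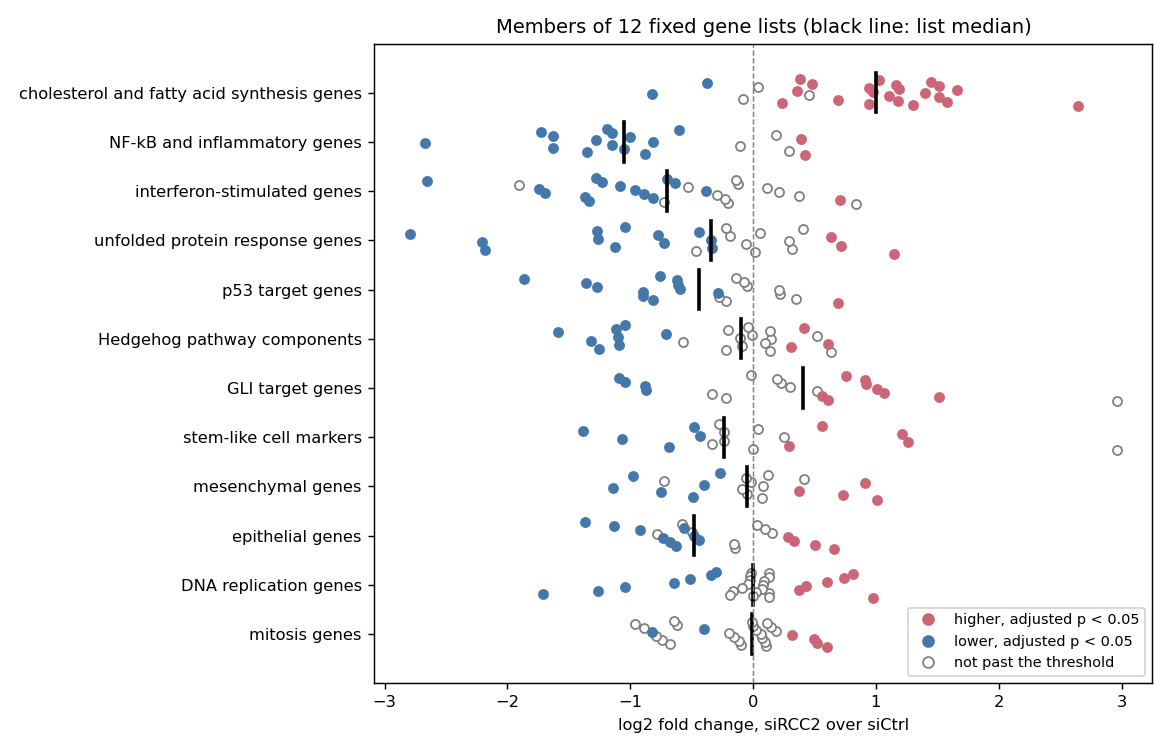
Log2 fold change of siRCC2 over siCtrl (horizontal axis) for the tested members of 12 fixed gene lists (vertical axis); each point is a gene, filled where its adjusted p is under 0.05, and black lines are list medians. The median is 1.00 for cholesterol and fatty acid synthesis and -1.05 for NF-kB and inflammatory genes, while 21 of 27 mitosis genes are open points.

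These 5 lists were the ones past the threshold among 32 tested by camera, which compares a list with other genes, and 0 passed with an estimated correlation. By fry, which asks whether a list's genes move on balance one way, 16 passed. Among them were the Hedgehog components, downward (adjusted p = 0.000140), and the GLI targets, upward (adjusted p = 0.00263). Another 4 lists had fewer than 5 tested members: 1 of 4 neuroendocrine markers fell (SYP, -1.71 ± 0.16), 0 of 2 leukocyte markers changed, the endothelial marker ESAM fell from 1.06 ± 0.183 to 0.415 ± 0.0506 CPM, and of the luminal prostate markers SLC45A3 fell (-0.93 ± 0.17). Of 6 fibroblast and stroma markers 1 rose and 2 fell (2 and 2 over the list alone; camera adjusted p = 0.631); ACTA2 fell from 1.75 ± 0.132 to 0.352 ± 0.2 CPM.

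Other lists did not pass as a whole. Of 24 immediate early genes 5 rose and 11 fell (8 and 12 over the list alone; camera adjusted p = 0.0770, and from 0.00945 to 0.0499 with each of the 3 other filters, with length offsets and with these and a replicate block), with EGR1 lower (257 ± 5.6 to 82.5 ± 2.56 CPM, -1.64 ± 0.06), DUSP1 lower (-1.33 ± 0.06) and JUN higher (1.25 ± 0.07). Of 26 DNA damage repair genes 0 rose and 12 fell, the same over the list alone (camera adjusted p = 0.0852, and 0.0335 without siRCC2 replicate 3 or 0.0116 with genes of at least 1 read kept), with BRCA1 (-1.11 ± 0.21) and FANCD2 (-0.58 ± 0.09) lower. Of 32 cytosolic ribosomal protein genes 1 rose and 8 fell (1 and 7 over the list alone; camera adjusted p = 0.0852, and 0.00275 without siRCC2 replicate 1, 0.0303 with total counts alone, 0.0102 with genes of at least 1 read kept or 0.0305 with a replicate block and length offsets), with RPS2 (-1.04 ± 0.09) and RPS23 (-0.54 ± 0.09) lower. Of 24 hypoxia and glycolysis genes 9 rose and 4 fell (camera adjusted p = 0.112, and 0.0486 without siRCC2 replicate 3), with PFKFB4 (1.71 ± 0.10) and ALDOC (2.10 ± 0.22) higher. Of 13 mitochondrially encoded messenger RNAs 4 rose and 0 fell (camera adjusted p = 0.160, and 0.0486 without siRCC2 replicate 3), with MT-ND5 higher (0.76 ± 0.08). Of 12 replication-dependent histone genes 6 rose and 1 fell (7 and 1 over the list alone; camera adjusted p = 0.0852, and 0.0486 without siRCC2 replicate 3). H2BC5 (1.29 ± 0.11) rose and H2BC12 (-0.98 ± 0.08) fell. Some RNAs without a poly(A) tail rose: RN7SL1 went from 27.4 ± 3.63 to 141 ± 6.97 CPM (2.37 ± 0.11) and the mitochondrial ribosomal RNA MT-RNR1 from 687 ± 17 to 1970 ± 51.6 CPM (1.52 ± 0.06). Of 15 other small structural RNAs and histone genes with a mean of at least 1 CPM, 9 rose, 1 fell and the rest did not pass.

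Signalling lists were mixed. Of 15 Wnt targets 2 rose and 4 fell (camera adjusted p = 0.486), with AXIN2 higher (1.15 ± 0.19) and NOTUM lower (-1.96 ± 0.18). Of 17 Notch genes 4 rose and 5 fell (5 and 5 over the list alone; camera adjusted p = 0.987), with MAML1 higher (0.97 ± 0.06) and LFNG lower (-1.53 ± 0.20); the median was 0.03, the mean -0.23 and the direction of the test down. Of 19 TGF-beta and BMP targets 7 rose and 5 fell (camera adjusted p = 0.389), with ID2 (1.91 ± 0.14) and LTBP2 (0.95 ± 0.06) higher. Of 27 apoptosis regulators 4 rose and 6 fell (camera adjusted p = 0.948), with BMF (-1.32 ± 0.13) and CASP9 (-0.91 ± 0.10) lower and BID (0.63 ± 0.10) and BAK1 (0.62 ± 0.10) higher; the median was 0.01, the mean -0.07 and the direction down. Of 8 genes of the androgen receptor list 1 rose and 3 fell (camera adjusted p = 0.948), with PMEPA1 lower (-0.71 ± 0.09). Of 18 genes of siRNA handling and double-stranded RNA sensing 1 rose and 5 fell (camera adjusted p = 0.418), with AGO4 (-0.86 ± 0.11) lower and DGCR8 (0.66 ± 0.10) higher. Of 24 nuclear respiratory chain genes 4 rose and 4 fell (camera adjusted p = 0.987), with COX7C (-1.23 ± 0.12) lower; the median was 0.03, the mean -0.01 and the direction up. For the lists in this paragraph and the hypoxia and mitochondrial lists, counts adjusted over the list alone were the same except where given. The medians of the Notch, apoptosis and respiratory chain lists were -0.04, -0.06 and -0.05 with total counts alone.

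A sequence in 3′ UTRs went with the falls, in a search made after the fold changes were seen. Over 12304 genes, TCTGGAA was the 7-mer with the lowest t statistic (-16.1) of 16174, followed by the overlapping CTCTGGA (-14.1), after adjustment for 3′ UTR length, base composition and expression. The highest statistic on the rising side was 4.98. The joint 8-mer CTCTGGAA was picked as the extension with the lowest median over all genes, and genes with it in the 3′ UTR had a median log2 fold change of -0.32 (671 genes). Genes with CTCTGGA or TCTGGAA but not the 8-mer had medians of -0.18 (1301 genes) and -0.19 (1264 genes), and those without the shared 6-mer TCTGGA had one of 0.03 (7476 genes). Of the genes with the 8-mer, 40.5% fell and 13% rose, and of those without the 6-mer 19.1% fell and 24.0% rose. Genes with the 8-mer in the coding sequence but not the 3′ UTR had a median close to that of the 3′ UTR group, -0.29 (911 genes, 37.1% fell). With 2 copies in the 3′ UTR the median was -0.20 (35 genes), nearer 0 than the -0.33 with 1 copy (631 genes). Either 7-mer was present in 26.3% of all genes searched and in 38.9% of the 2917 that fell. SUFU, FUT1, MYZAP, CDH3, MCM10 and BMF hold the 8-mer, and so does SNAI1, which rose. CCND1, TNFRSF10B, LIF and KRT7 hold TCTGGAA, while ASNS, DDIT4, KRT81, STAT2, NFKB2 and GLI1 hold no 6-mer in the 3′ UTR. The longest RCC2 coding transcript (4087 bases) holds CTCTGGA at positions 1627 to 1633, in the coding sequence, and TCTGGAA at positions 37 to 43, in the 5′ UTR.

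**Figure D3:**
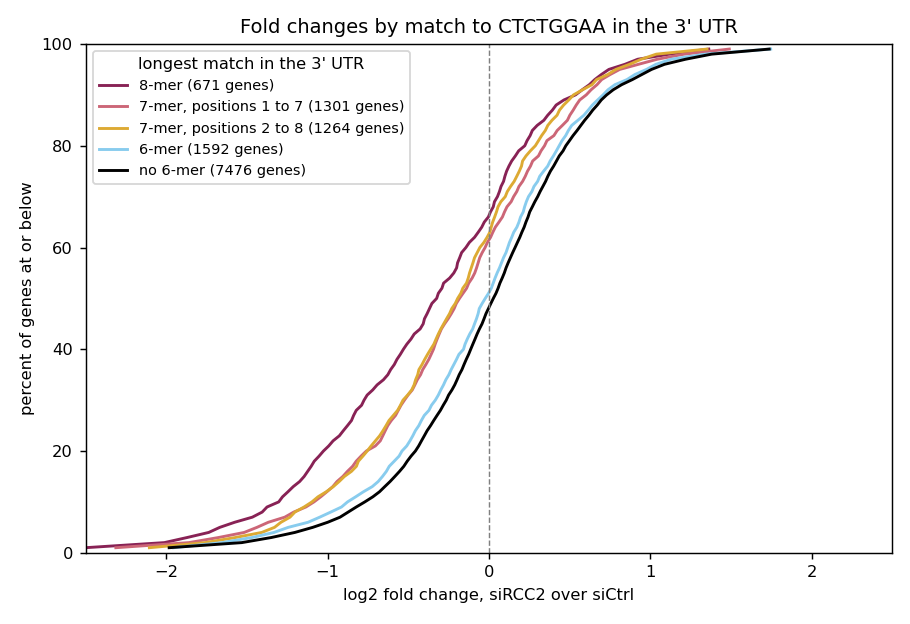
Percent of genes at or below each log2 fold change of siRCC2 over siCtrl (vertical against horizontal axis), for genes grouped by their longest match to CTCTGGAA in the 3′ UTR. The curve of the 671 genes with the 8-mer lies to the left (median -0.32), those with a 7-mer follow (-0.18 and -0.19), and the 7476 genes without the 6-mer lie to the right (0.03).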

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

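Tests with length or GC offsets and without the 6-mer were added after the data were seen. The count of 6911 changed genes ranged from 5112 to 7565 when 1 library was left out and from 5431 to 7018 over the scalings, tests, filters, offsets and blocks. It was 4117 at an adjusted p under 0.01. Among the 3151 genes without the 6-mer, the counts were 1491 changed, 983 higher, 508 lower and 341 changed at least 2-fold, from fewer genes tested. Higher genes were 49.5% of the calls, and 42.8% with total counts alone, which moved the median of all genes to -0.08.

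RCC2 fell in each fit that included it; it holds the 6-mer and so was not among the genes without it. Of the 32 lists tested, 5 passed; the count was 11 with genes of at least 1 read kept, 3 among genes without the 6-mer, 0 with an estimated correlation and 16 by fry. Leaving out 1 library gave 5 to 10 lists, the 10 without siRCC2 replicate 3; the cause was not tested. With an estimated correlation the adjusted p was 0.0532 for cholesterol and fatty acid synthesis, 0.106 for NF-kB and inflammatory genes, 0.157 for interferon-stimulated genes and 0.30 for both the unfolded protein response and p53 lists. The interferon list was at 0.0546 among genes without the 6-mer, where 5 members were left. In the other runs these 5 lists stayed past the threshold in their direction, where at least 5 members remained.

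With the replicate number as a block, 6295 genes changed (5431 by DESeq2 with the block), and 6025 of the 6911 were shared in direction. Deviations of libraries with the same number correlated at 0.06, -0.04 and 0.10 across genes, the last being the highest of any pair across the groups. For siRCC2 replicate 1 the value was 0.062 with siCtrl replicate 2 and 0.059 with siCtrl replicate 1. Such values do not decide for or against pairing. The labels do not state it, so the numbers were not taken to pair the samples.

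Over 162 named genes, 16 of 2288 values lost the threshold, as did 18 of 972 when 1 library was left out. Of these values, 0 changed sign where either fit passed the threshold. Another 8 and 4 values, of MT-ND4, MT-CO2 and GAPDH, changed sign where neither fit passed it. COL1A1 and COL3A1 lost it in 11 and 9 settings and SMO in 8. Runs on unrounded counts, on TPM or FPKM, on another pseudocount and with gene lengths from the files were not run, since the files hold whole counts without lengths.

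The 6 libraries split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 6911 changed genes and 1993 changed at least 2-fold, against at most 1 in any other split, 3423 higher and 3488 lower against at most 1 in one direction, and 5 lists against at most 3. In each case 1 of the 10 splits, the real one, gave a result that large. Each other split mixes siCtrl and siRCC2 libraries, which puts the difference between the groups into the spread within each side. Few changed genes would follow there whatever the cause, so these splits do not test chance.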

Other observations

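The following lists and genes were chosen after the largest changes were seen, and p-values were adjusted over these 8 lists alone, so they do not compare with those of the 32 fixed lists. Genes that charge transfer RNAs in the cytosol fell: of 20 aminoacyl-tRNA synthetase genes 14 fell and 3 rose (median -0.75, camera adjusted p = 1.25e-09, and adjusted p = 0.0177 with an estimated correlation). TARS1 fell by 1.82 on the log2 scale, MARS1 by 1.69 and GARS1 by 1.32. Of the 17 genes for the mitochondrial enzymes 4 fell and 1 rose (adjusted p = 0.648). Serine synthesis and one-carbon genes fell in 10 of 15 cases and rose in 1 (adjusted p = 2.14e-06, and adjusted p = 0.0440 with an estimated correlation), with PSAT1 at -1.89 ± 0.06 and PHGDH at -1.13 ± 0.08. Amino acid transporter genes fell in 12 of 22 cases and rose in 3 (adjusted p = 3.50e-05, and adjusted p = 0.0366 with an estimated correlation), with SLC7A5 at -1.67 ± 0.07 and SLC1A4 at -2.43 ± 0.08. Of the 12 fallen synthetase genes whose 3′ UTR could be searched, 1 holds either 7-mer of the motif there, as do 4 of 10 fallen serine and one-carbon genes and 3 of 11 fallen transporter genes.

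Aldo-keto reductases were among the NRF2 targets that rose, 11 of 27 with 5 lower (adjusted p = 0.000314, and adjusted p = 0.213 with an estimated correlation; median 0.08, mean 0.42; adjusted p = 0.966 among the 10 members without the 6-mer): AKR1C2 rose by 2.57 ± 0.10 and AKR1B10 by 2.24 ± 0.16, while NQO1 had 0.17 ± 0.08 and GCLM -0.21 ± 0.13. Of 12 keratin genes 7 fell and 4 rose (adjusted p = 2.86e-06, and adjusted p = 0.0711 with an estimated correlation). Type IV collagen and laminin genes (9 rose and 4 fell of 18, adjusted p = 0.431; COL4A1 2.25 ± 0.08) and MHC class I genes (3 rose and 6 fell of 17, adjusted p = 0.435; B2M 1.11 ± 0.07, TAP1 -1.66 ± 0.09) did not pass as lists. MYC had 61, 62 and 72 counts in siCtrl and 133, 59 and 1288 in siRCC2 replicates 1 to 3, and did not pass; 1 library sets this spread, and its cause was not tested.

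The tests of the 3′ UTR sequence, of RNA without a poly(A) tail, of mitochondrial RNA as a whole and of mixed-in control RNA were chosen after results were seen. For the first pattern, genes lower in siRCC2, the 7-mer found on even-numbered chromosomes, TCTGGAA, ranked 1 among all 7-mers on the odd-numbered chromosomes and X, where genes with it lay -0.32 from those without (permutation p = 0.0001, the smallest 10000 permutations can give). Of the anagrams of the motif 0.159% (only itself, 1 of 630) went with a fall as large. That count was fixed in advance, since TCTGGAA had the lowest t statistic of all 7-mers over these same genes. It therefore cannot decide whether base composition plays a part. The rank on the odd-numbered chromosomes and X was not fixed in this way, and no anagram scored there had a lower t. These values are consistent with an siRNA acting through its seed region on many messenger RNAs, with CTCTGGA in the RCC2 coding sequence a candidate target site, but the siRNA sequences are not given in the sources used here and no second siRNA was tested. Yet 15.2% of the 3151 genes without the 6-mer in their transcript fell, so a match to this 6-mer there does not account for all falls. Only the longest coding transcript of each gene was searched. Matches in other transcripts, or to another seed, stay open. For SUFU and CCND1, which hold a match, loss of RCC2 and a seed effect both stay open. The same holds for GLI1, whose transcript holds the 6-mer outside the 3′ UTR. That match is common and says little about GLI1. Of the 12304 genes searched, 9153 hold the 6-mer in their transcript, and 26.6% of these fell. Genes with the 8-mer in the coding sequence but not the 3′ UTR lay almost as low (-0.29) as those with it there, with no larger fall for 2 copies, so a role of the 3′ UTR in particular stays open. These medians were not adjusted for length, base composition or expression. Genes of the coding group may also hold a 7-mer or the 6-mer in the 3′ UTR.

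The second pattern is the rise of RN7SL1, RN7SL2, RN7SL4P and the mitochondrial ribosomal RNAs. Their lowest log2 fold change over the other scalings was 0.78, so the choice among these scalings does not account for the rise. This outcome was nearly fixed in advance, since the median of all genes lay only between -0.083 and -0.001 under them. It does not test scaling of another kind. The 13 mitochondrial messenger RNAs had a median of 0.11, below MT-RNR2 (0.85), which argues against more mitochondrial RNA as a whole. The other 15 small structural RNAs and histone genes had a median of 0.66 (95% bootstrap interval 0.10 to 1.10), and 9 rose and 1 fell. This median pools unlike groups. The small structural RNAs lay from 0.66 to 2.96 (RPPH1, called uncertain above), the histone genes from -0.98 to 1.29. More carry-over of RNA without a poly(A) tail therefore cannot be told apart from a change in the cells. Carry-over would apply only if RNA with a poly(A) tail was selected, which the sources used here do not say. A biological change after RCC2 siRNA stays open and was not tested.

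The third pattern is that siRCC2 replicate 1 stands apart from replicates 2 and 3. Its deviation from them correlated with transcript GC content at r = 0.434 across genes, against -0.12 to 0.07 in the siCtrl libraries, as a GC-dependent step in library making may give. Replicates 2 and 3 had r of -0.145 and -0.380, so a GC trend of replicate 3 is not ruled out, since each deviation is taken in part from the others; genes are not independent replicates. Its smaller total is not the whole account, since after thinning to equal totals its distance from its group members was 1.30 times that between them. Mixed-in control RNA is argued against as the source of the difference, though not as a small share: 1.30% of the variance of its deviation lies along the axis between the groups, the direction mixing gives, the third test tried after results were seen. The earlier ones read its position on that axis (0.913, with replicates 2 and 3 at 0.883 and 0.797), which fixed bounds left open and a ranking against its group members did not.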
